A study of Mus musculus with 7 samples.

How the data were processed

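RNA was measured in EpCAM-positive cells sorted from 7 mouse colon tumours, 4 grown from P1 and 3 from P5 AKPS organoids, with each tumour from its own mouse. Libraries were prepared with a stranded mRNA kit and sequenced as single-end reads, per the labels' protocols. The authors deposited a table of raw counts per Ensembl gene, with 52636 genes and 1 column per library. They also deposited a table of log2 CPM for 17919 genes. GSNAP, edgeR, limma and the genome build GRCm38.p5 are named in the submitters' processing notes. The counting program, the annotation release, strand setting and versions are not given in the sources used here. The deposited log2 values were recomputed from the counts with TMM factors and a prior count of 3 within 0.000822, and their 17919 genes were those that edgeR's filterByExpr kept. Columns were matched to samples through the library names in the labels.

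Library totals were 41275669, 44112864, 36728958 and 39914273 counts for P1 replicates 1 to 4 and 47357597, 44317471 and 42589787 counts for P5 replicates 1 to 3. TMM factors ran from 1.02 to 1.07 in P1 and from 0.928 to 0.941 in P5. A count of 0 was given an upper limit of 3 counts per library for bounds on folds. Replicate libraries differed by more than sampling noise, with chi-square values per degree of freedom of 22.2 to 79.4 between pairs of a group, so no library was counted as a repeat of another.

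Differential expression was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes, and log2 fold changes are P5 minus P1 with standard errors from the F statistic. A total of 52 gene lists with 871 members (pathways, intestinal lineages and cells a sort could carry over) were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 52 lists. Camera with an estimated correlation and fry were the checks, and no list passed with an estimated correlation (lowest adjusted p = 0.367, with 3 of 52 at an unadjusted p under 0.05), whereas fry's directional test passed 38 lists. The median, mean and test had the same direction in all 21 lists that passed camera. Among the lists that did not pass, they differed in sign for gastric, p53, engineered, cell cycle inhibitor and heat shock genes.

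Symbols, positions, GC content and exon lengths came from GENCODE M21 (GRCm38), matched by Ensembl identifier. Symbols were found for 52403 of 52636 genes and for 17888 of 17919 tested genes. Named genes were chosen by a rule fixed before the data were examined. It takes the 10 rising and 10 falling genes with the largest absolute log2 fold change among genes past the threshold with a mean log2 CPM of at least 3 and CPM ranges that do not overlap, leaving out predicted (Gm or Rik), immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes. It adds the 4 engineered genes, all MAPK activity score genes, and up to 4 members past the threshold of every other list in order of p, or the 2 with the highest CPM where fewer than 2 passed. Other list members named as examples, and genes named outside the lists, were chosen after their values were seen.

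Alternatives were DESeq2 size factors (RLE), upper-quartile and total-count scaling, no low-count filter, a filter at CPM 1 in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on the deposited log2 CPM, robust shrinkage, an added 2-fold threshold, the replicate number as a block, leaving out each library, and a covariate of leukocyte, macrophage, fibroblast and endothelial markers. Covariates of 8 posterior Hox genes and of leukocyte and macrophage markers were added after the data were seen. The steps were tested on simulated counts drawn from the real means, dispersions and library sizes with 200 changed genes. Of these, 13.5% were recovered at a fold of 1.5 (17512 genes tested), 58.0% at 2 (17504 genes) and 78.5% at 4 (17480 genes), with 2, 8 and 7 false calls. With no gene changed, camera called 0 of 52 lists. With 1 list raised 1.5-fold, camera called 2 of 52, the raised list among them. The means, dispersions and library sizes used for the draws carry no correlation between genes, so these list calls do not test the preset inter-gene correlation. In the real comparison edgeR called 8399 genes at the same threshold, against 200 changed genes in the simulation. The recovery rates therefore do not give the share of changes found in the real comparison.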

Results

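RNA-seq was performed on live EpCAM-positive (epithelial) cells sorted from mouse colon tumours. The tumours grew from AKPS organoids, which are small-intestinal epithelial cultures with mutations in Apc, Kras, Trp53 (Tp53) and Smad4. These organoids had been passaged through mice in sequence, and organoids of passage 1 (P1) or passage 5 (P5) were placed in the colon wall of C57BL/6N mice, 10000 organoids per mouse. Tumours were taken 5 weeks later, from 4 mice for P1 and 3 mice for P5. The series title names MAPK and Wnt signalling, and the design gives 1 comparison, P5 against P1 tumours. Each passage was represented by 1 organoid line, so the mice are replicates of a line, and passage cannot be separated from line. Library totals ran from 36728958 to 47357597 counts, at which 3 counts correspond to 0.0638 to 0.0764 CPM (counts normalised to library size). Counting intervals and floors given below cover counting error only, and bootstrap intervals cover only the spread over the genes of a list.

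The 2 groups differed across a large part of the transcriptome. Of 17919 genes tested, 8399 (46.9%) passed an adjusted p of 0.05, 3965 of them higher and 4434 lower in P5 tumours. With a change of more than 2-fold in addition, 1078 genes were higher and 2621 lower. The CPM ranges of the groups did not overlap for 9339 genes (52.1%), where chance gives 5.71%. The first principal component held 73.9% of the variance and separated P1 from P5. Correlations of log2 CPM across genes were 0.9751 to 0.983 between tumours of a group and 0.910 to 0.923 between groups (genes are not independent replicates). With scaling to total counts in place of TMM, the log2 fold changes moved by a median of -0.166, and 2718 genes were higher and 5883 lower (31.6% higher, against 47.2% with TMM). The count dropped to 3015 genes with the mean log2 CPM of posterior Hox genes as a covariate and to 2474 with leukocyte and macrophage markers as a covariate, both chosen after the data were seen, and to 4202 with a covariate over leukocyte, macrophage, fibroblast and endothelial markers (the non-epithelial covariate below). These covariates differ between the groups.

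The genes with the largest rise in P5 tumours among well-expressed genes included a tight junction claudin, a trefoil factor and a T-box transcription factor. Cldn6 (ENSMUSG00000023906, chromosome 17, 23679249 to 23682446, GRCm38), a claudin known from embryonic epithelia, was at 0.894 ± 1.15 CPM (SD, n = 4) in P1 and 851 ± 46.2 CPM (n = 3) in P5. Tff1, a trefoil peptide of gastric surface mucous cells (chromosome 17, 31161395 to 31165277), went from 6.24 ± 3.38 to 540 ± 113 CPM. Eomes, a T-box factor of early embryo and lymphocytes, went from 1.16 ± 0.231 to 81.5 ± 9.38 CPM. Ptges, the inducible prostaglandin E synthase, rose by 5.38 ± 0.21 (SE) on the log2 scale to 565 ± 16.2 CPM. The adaptor gene Efs, the membrane glycoprotein gene Gpm6b, Trip6, the peptidylarginine deiminase gene Padi2, Prune2 and the keratin gene Krt78 rose by 5.12 to 6.20 log2 units. The adjusted p-values of these 10 genes lay between 9.16e-08 and 1.71e-05.

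The 10 well-expressed genes with the largest fall had P5 values at or near 0. Pitx2, a homeobox gene of left-right patterning (ENSMUSG00000028023, chromosome 3, 129199878 to 129219591), had 68.9 ± 12.5 CPM in P1 and no count in any P5 tumour, at least 959-fold lower against a floor of 3 counts per library. Against the same floor, Bpifb1 was at least 641-fold lower, the homeobox gene Irx3 at least 586-fold, Bpifb5 at least 289.6-fold, the sodium channel gene Scn5a at least 249-fold and the Paneth cell defensin gene Defa24 at least 221-fold. Amer2, an APC-binding protein, had 2736 counts in the P1 tumours together and 2 in the P5 tumours, a ratio of 1010 with a 95% counting interval of 279 to 8350. Erich3 had 2619 and 2 counts, a ratio of 967 (interval 267 to 7990). The kallikrein gene Klk8 fell from 93.4 to 0.0544 CPM, and the growth factor gene Ptn (pleiotrophin) from 325 ± 125 to 0.276 ± 0.141 CPM.

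Of the 4 engineered genes, Kras passed the threshold. Kras (chromosome 6, 145216699 to 145250239) was at 256 ± 31.2 CPM in P1 and 352 ± 7.42 CPM in P5, a log2 fold change of 0.46 ± 0.10 (SE, adjusted p = 0.00503). Its call was lost with the covariate over non-epithelial markers (0.320) and with that over leukocyte and macrophage markers (0.453), the range over alternatives being 0.000269 to 0.453. Among genes with a mean log2 CPM above 3, the median log2 fold change was 0.43 on chromosome 6 and 0.456 between its 140 and 160 Mb. The rise of Kras was thus about that of the genes around it. Apc (chromosome 18, 34220924 to 34322552) was at 96.8 ± 18.0 and 93.6 ± 12.2 CPM, Trp53 (chromosome 11, 69580359 to 69591873) at 61.7 ± 2.002 and 58.2 ± 2.67 CPM, and Smad4 (chromosome 18, 73639009 to 73703780) at 208 ± 23.1 and 213 ± 22.5 CPM, with adjusted p-values of 0.817, 0.398 and 0.831. Counts per gene carry no sequence of the mutations, so they do not check the engineered alleles.

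Transcripts downstream of MAPK signalling were mostly higher in P5 tumours. Of 28 measured ERK targets and feedback regulators, 16 rose, 4 fell and 8 did not pass (16 and 5 when adjusted over the list alone), and the list was higher by camera (adjusted p = 0.00368). Fosl1, an AP-1 subunit (chromosome 19, 5447547 to 5455946), went from 59.3 ± 4.05 to 118 ± 5.22 CPM, and Myc from 199 ± 18.7 to 382 ± 28.6 CPM. On the log2 scale these rises were 0.99 and 0.94. Genes around them with a mean log2 CPM above 3 had medians of 0.466 (chromosome 19, 0 to 20 Mb) and 0.373 (chromosome 15, 60 to 80 Mb). The immediate-early gene Ier3 rose by 1.31 ± 0.13 on the log2 scale, the ephrin receptor gene Epha2 by 1.12 ± 0.13 and the cytokine gene Il1a by 2.19. Etv5, Phlda1, Hmga2 and Elf1 fell, Etv5 from 82.5 ± 18.1 to 35.2 ± 4.87 CPM. The ERK phosphatase gene Dusp6 was at 339 ± 35.2 and 361 ± 8.76 CPM and Ccnd1 at 214 ± 14.3 and 219 ± 19.3 CPM, neither past the threshold. The list's adjusted p was 0.560 with an estimated correlation and 0.465 with the Hox covariate. With that covariate Epha2, Epha4, Dusp4 and Spry4 no longer passed and had smaller log2 fold changes (0.48, 0.36, 0.13 and 0.45), and Etv5 and Phlda1 no longer passed with log2 fold changes that were no smaller (-1.26 and -0.55). Of the 35 ways to split the 7 tumours into 4 and 3, 10 gave this list a camera p as small as the real one. The other splits carry part of the P5 against P1 contrast, so this count cannot decide on chance.

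The shorter list of 10 MAPK pathway activity score genes did not pass (camera adjusted p = 0.324). In it Epha2, Epha4, Dusp4, Spry4 and Etv4 rose, Etv5 and Phlda1 fell, and Spry2, Dusp6 and Ccnd1 did not pass, the same numbers as when adjusted over the list alone. Epha4 rose by 0.63 ± 0.08, Dusp4 by 0.59 ± 0.12 and Spry4 by 0.62 ± 0.12 on the log2 scale. Phlda1 fell by 0.52 ± 0.09. The call of Etv4 (0.23 ± 0.09, adjusted p = 0.0481) was lost in most alternatives, for example with DESeq2 size factors (0.0602, range over alternatives 0.0398 to 0.870). Among 11 EGFR ligands and receptors, 5 rose and 2 fell (5 and 2 when adjusted over the list alone) and the list did not pass (adjusted p = 0.0818). The EGFR ligand genes Btc, Tgfa and Areg rose, Btc from 60.5 ± 2.31 to 139 ± 7.77 CPM and Tgfa from 148 ± 25.9 to 356 ± 5.16 CPM. The receptor gene Egfr rose from 70.4 ± 4.18 to 94.2 ± 5.24 CPM.

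Wnt target genes were lower in P5 tumours as a list. Of 26 measured genes, 16 fell, 3 rose and 7 did not pass (17 and 3 when adjusted over the list alone), with a camera adjusted p of 9.08e-09. Nkd1, a negative feedback regulator of the pathway (ENSMUSG00000031661, chromosome 8, 88521354 to 88594884), fell from 528 ± 58.7 to 2.34 ± 0.623 CPM. Prox1, a homeobox gene, fell from 179 ± 48.1 to 0.512 ± 0.316 CPM and Wif1, a secreted Wnt inhibitor, from 86.7 ± 24.5 to 0.432 ± 0.160 CPM. Wnt6 fell by 3.79 ± 0.23, Apcdd1 by 3.65 and the transcription factor gene Lef1 by 1.79 on the log2 scale. Lgr5, a receptor of R-spondins and stem cell marker, fell by 0.53. Myc, Tcf7 and Cd44 rose. The feedback genes Axin2 (114 against 99.6 CPM), Rnf43 (276 against 211) and Znrf3 (50.5 against 42.1) and the stem cell factor gene Ascl2 (26.4 against 28.6) did not pass. The list had an adjusted p = 0.466 with an estimated correlation.

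**Figure D1:**
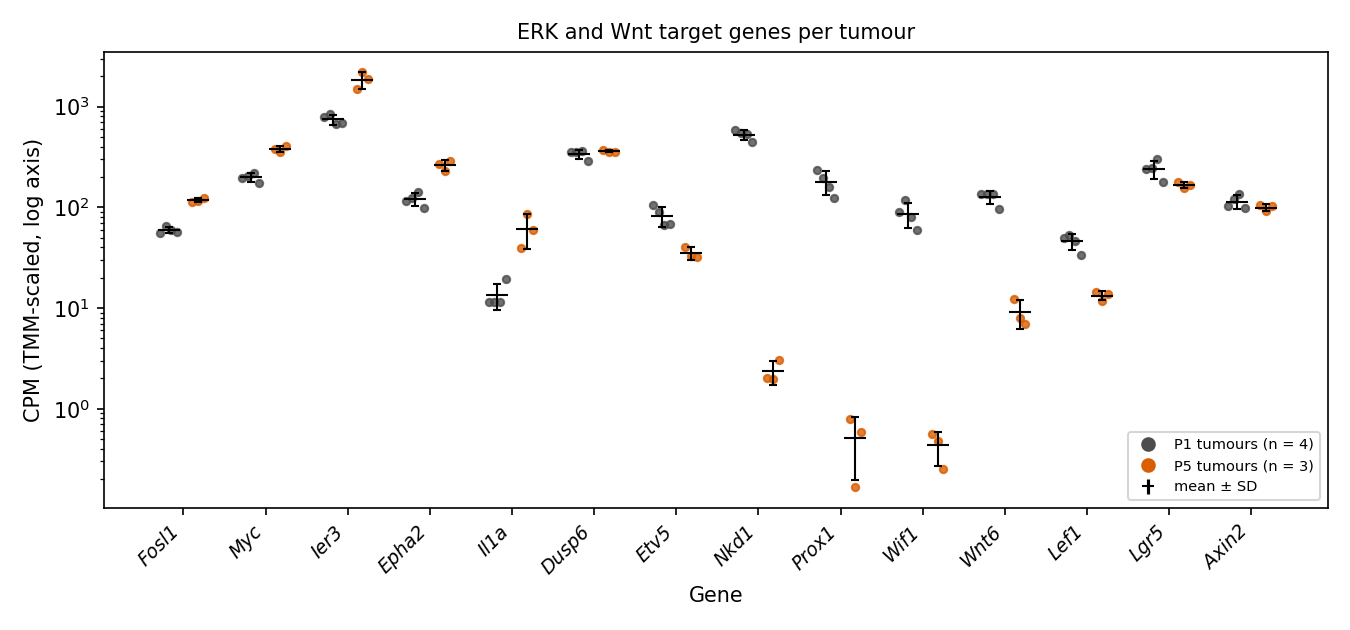
CPM per tumour (log axis) of 7 ERK target genes, Fosl1 to Etv5, and 7 Wnt target genes, Nkd1 to Axin2, in P1 (grey, n = 4) and P5 tumours (orange, n = 3). Each point is a tumour, and bars give the mean ± SD. Nkd1 lies near 528 CPM in P1 and 2.34 CPM in P5, and Dusp6 and Axin2 overlap between the groups.

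Wnt pathway components moved in both directions. Of 25 Wnt ligands, receptors and secreted antagonists, 16 fell and 6 rose (16 and 6 when adjusted over the list alone), with a camera adjusted p of 0.000241 and an adjusted p of 0.466 with an estimated correlation. Besides Wif1 and Wnt6, the ligand gene Wnt11 fell by 4.02 ± 0.32 and the Frizzled receptor gene Fzd9 by 3.63 ± 0.21. The 6 genes that rose were Wnt7b, the co-receptor genes Lrp5 and Lrp6, Fzd1, Fzd6 and Fzd7, Wnt7b from 300.3 to 717 CPM. Intestinal stem cell genes did not pass as a list (2 rose, 6 fell, 9 did not pass, with 2 and 6 when adjusted over the list alone, adjusted p = 0.261). Smoc2, a matrix protein of Lgr5-expressing cells, fell from 1307 ± 149.8 to 24.3 ± 10.01 CPM and Prom1 from 1545 ± 107 to 913 ± 27.8 CPM, whereas Igfbp4 rose from 306 ± 32.8 to 653 ± 49.7 CPM and Cdk6 by 1.28 ± 0.17 on the log2 scale.

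Paneth and goblet cell genes were lower in P5 tumours. The lists of 2 other secretory cell types, enteroendocrine (3 of 12 genes lower, camera adjusted p = 0.183) and tuft cells (8 of 12 lower, 2 higher, 0.261), did not pass camera. By fry both were lower (adjusted p = 0.0315 and 0.0350). Their median log2 fold changes were -0.83 and -2.62, against -1.82 for the goblet list. All 12 measured Paneth cell genes fell (12 when adjusted over the list alone), with a camera adjusted p of 1.09e-12. Their median log2 fold change was -7.16, or -5.36 with the 4 members at 0 in every P5 tumour set at their bound. The antimicrobial phospholipase gene Pla2g2a (chromosome 4, 138831857 to 138835186) fell from 324 ± 37.8 to 4.27 ± 1.23 CPM, Reg3g from 37.3 ± 8.12 to 0.0963 ± 0.0639 CPM and Itln1 from 77.2 ± 32.2 to 0.315 ± 0.385 CPM. Of 14 goblet cell genes, 13 fell and 1, Bcas1, rose (13 and 1 when adjusted over the list alone), with a camera adjusted p of 9.08e-09. The trefoil gene Tff3 (chromosome 17, 31125306 to 31129646) fell from 422 ± 14.8 to 90.8 ± 8.84 CPM, Zg16 from 492 ± 70.9 to 137 ± 8.62 CPM and Atoh1, the transcription factor of the secretory lineage, from 40.0 ± 2.50 to 7.79 ± 2.25 CPM. The adjusted p was 0.367 with an estimated correlation for the Paneth and 0.466 for the goblet list.

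Markers of the host colon also moved with the groups. Of 19 colon epithelium genes, 13 fell and 6 did not pass (17 fell when adjusted over the list alone), with a camera adjusted p of 0.00479 and an adjusted p of 0.600 with an estimated correlation. Hoxb13, a homeobox gene of the distal gut, was at 118 to 243 CPM in the P1 tumours and 44.3 to 85.3 CPM in the P5 tumours, a log2 fold change of -1.54 ± 0.31. Xist, chosen after its values were seen, moved likewise, from 22.3 ± 5.67 to 6.93 ± 4.19 CPM.

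Antigen presentation and interferon response genes were lower in P5 tumours. Of 16 MHC class I presentation genes, 14 fell and 2 did not pass (14 when adjusted over the list alone, camera adjusted p = 4.41e-08). B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), fell from 456 ± 33.7 to 147 ± 19.05 CPM, the immunoproteasome subunit gene Psmb8 by 3.00 ± 0.25 and Psmb9 by 2.83 ± 0.27 on the log2 scale. The heavy chain genes H2-D1 and H2-K1 fell by 0.92 and 0.51. Of 7 MHC class II genes, 6 fell (7 when adjusted over the list alone, camera adjusted p = 0.000172), Cd74 (chromosome 18, 60803848 to 60812652) from 109 ± 55.1 to 1.46 ± 0.758 CPM. Of 25 type I interferon response genes, 22 fell and 1 rose (22 and 1 when adjusted over the list alone, camera adjusted p = 4.16e-08), and of 22 interferon gamma response genes, 19 fell and 1 rose (19 and 1, camera adjusted p = 1.56e-06). Stat1 fell by 1.89 ± 0.17, Bst2 by 2.49 ± 0.16, Usp18 by 3.41 ± 0.28 and Irgm2 by 2.46 ± 0.26. Each of these 4 lists had an adjusted p of 0.466 with an estimated correlation.

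Single markers of leukocytes and macrophages were lower in P5 tumours, most of them at low levels, but neither list passed camera, and Cd53 (18.3 ± 2.93 to 40.1 ± 8.30 CPM) and Mrc1 (3.99 ± 1.12 to 11.04 ± 3.38 CPM) rose. By fry both lists were lower (adjusted p = 0.0391 for leukocytes and 0.0268 for macrophages). With the leukocyte and macrophage covariate 7 of the 14 class I and 11 of the 40 interferon genes that fell still passed. The median log2 fold changes of these genes were -1.98 without and -1.67 with that covariate for class I and -2.48 and -2.59 for interferon genes, the median standard errors more than doubled, and the lists still passed camera (adjusted p at most 3.08e-05 and 0.00208). Of 11 leukocyte genes, 7 fell and 1 rose (camera adjusted p = 0.199), and of 12 macrophage and monocyte genes, 7 fell and 1 rose (adjusted p = 0.0899). Counts adjusted over the list alone were 8 lower and 1 higher for leukocytes and 7 lower and 1 higher for macrophages. Lyz2 was at 31.5 ± 30.2 and 0.672 ± 0.290 CPM, with 76.8 CPM in P1 replicate 2, and Lcp1 at 4.75 ± 1.34 and 1.36 ± 0.486 CPM. Endothelial genes (8 fell and 2 rose, 9 and 2 when adjusted over the list alone, adjusted p = 0.205) included Pecam1, which fell by 2.34 ± 0.37, and none of 13 fibroblast genes passed (edgeR, adjusted p = 0.844 for the list). No fibroblast gene passed when adjusted over the list alone, at an unadjusted p of 0.05, in DESeq2 or in limma-voom, and Col3a1 was at 133 ± 76.6 and 151 ± 113 CPM.

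**Figure D2:**
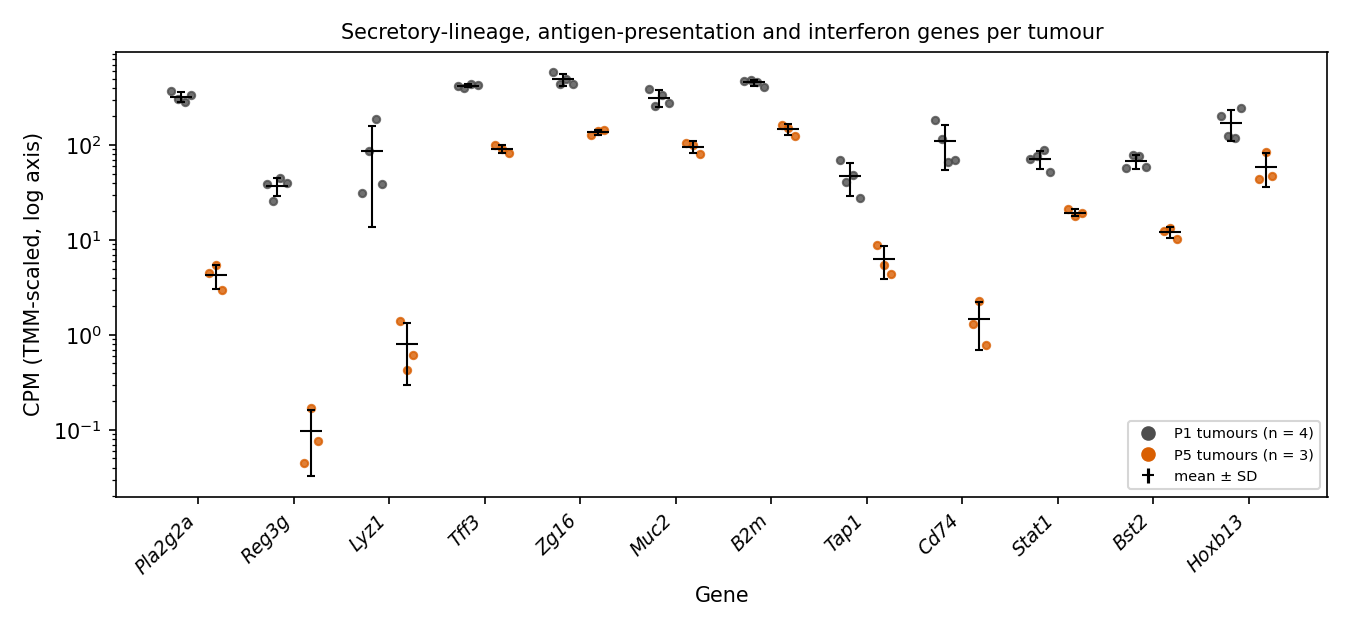
CPM per tumour (log axis) of Paneth, goblet, antigen presentation, interferon and host colon genes in P1 (grey, n = 4) and P5 tumours (orange, n = 3), with bars for the mean ± SD. All 12 genes lie lower in P5, and Hoxb13, the colon marker at the right, by 1.54 on the log2 scale.

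Cell cycle genes were higher in P5 tumours. Of 21 S phase and E2F genes, 17 rose and none fell (17 when adjusted over the list alone, camera adjusted p = 5.63e-09), among them Uhrf1, from 37.1 ± 0.554 to 90.7 ± 5.59 CPM, and the replication licensing genes Mcm2 and Mcm3, by 1.35 ± 0.11 and 1.10 ± 0.09 on the log2 scale. Of 20 G2 and M phase genes, 13 rose and none fell (13 when adjusted over the list alone, adjusted p = 6.76e-05), Bub1 from 28.4 ± 3.05 to 67.7 ± 4.61 CPM. Both lists had an adjusted p of 0.466 with an estimated correlation. The call of the G2 and M list was lost with the non-epithelial covariate (0.0662) and the leukocyte and macrophage covariate (0.332).

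Genes of glucose, lipid and redox metabolism were higher as well. Of 19 glycolysis genes, 16 rose (16 when adjusted over the list alone, camera adjusted p = 9.08e-09), Tpi1 from 774 ± 87.7 to 1926 ± 146 CPM and the pyruvate kinase gene Pkm from 511 ± 35.8 to 948 ± 42.9 CPM. Of 17 hypoxia genes, 14 rose (16 when adjusted over the list alone, adjusted p = 1.65e-07), Ndrg1 from 296 ± 56.9 to 1611 ± 382 CPM. Of 20 cholesterol synthesis genes, 12 rose and 1 fell (13 and 1 when adjusted over the list alone, adjusted p = 2.97e-05), with Cyp51 rising from 306 ± 24.9 to 1039 ± 95.3 CPM and Pcsk9, a SREBP target that lowers the LDL receptor, by 2.15 ± 0.10. Of 14 fatty acid synthesis genes, 8 rose and 1 fell (9 and 3 when adjusted over the list alone, adjusted p = 0.00172), the desaturase gene Scd1 from 37.6 ± 9.82 to 140.1 ± 3.07 CPM. Of 17 glutathione and NRF2 genes, 12 rose (13 when adjusted over the list alone, adjusted p = 0.000141), the cystine transporter gene Slc7a11 from 31.4 ± 6.88 to 231 ± 20.2 CPM. The adjusted p with an estimated correlation was 0.466 for the glycolysis, hypoxia and fatty acid lists and 0.528 for the cholesterol and glutathione lists. The calls of the cholesterol and fatty acid lists (0.0759 each) and the glutathione list (0.103) were lost with the non-epithelial covariate, and likewise with the leukocyte and macrophage covariate (0.0903, 0.0903 and 0.0986).

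Inflammatory transcripts moved in both directions. Of 20 NF-kappaB targets, 11 rose and 3 fell (11 and 4 when adjusted over the list alone, camera adjusted p = 0.00172), Tnfaip3, a feedback inhibitor of the pathway, from 132 ± 25.5 to 547 ± 108 CPM and the neutrophil chemokine gene Cxcl1 from 126 ± 15.5 to 528 ± 127 CPM. Of 27 chemokines and cytokines, 12 rose and 10 fell (12 and 10 when adjusted over the list alone, adjusted p = 0.0417). Csf2, which encodes GM-CSF (chromosome 11, 54247271 to 54249667), rose from 19.4 ± 3.72 to 218 ± 39.3 CPM, Csf3 by 2.54 ± 0.13 and Cxcl3 by 3.23 ± 0.22, whereas Ccl9 fell by 3.39 ± 0.22 and Csf1 by 1.76. Both had an adjusted p of 0.466 with an estimated correlation. The chemokine list lost its call without P1 replicate 1 (0.0534) or P1 replicate 3 (0.0827) and with the non-epithelial (0.176) and the leukocyte and macrophage covariates (0.0617).

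TGF-beta and BMP targets were lower as a list, with 12 of 20 lower and 5 higher (12 and 5 when adjusted over the list alone, camera adjusted p = 0.00172). The ligand gene Bmp7 fell from 99.7 ± 17.7 to 0.279 ± 0.0755 CPM, Bambi, a pseudoreceptor, by 2.75 ± 0.20, and Inhba by 2.96 ± 0.23, whereas Id2 rose by 1.73 ± 0.10. Of 20 genes of fetal-like and regenerative epithelium, 11 rose and 5 fell (11 and 5 when adjusted over the list alone, adjusted p = 0.0434). Emp1 rose from 1062 ± 141 to 3074 ± 146 CPM and Krt7 from 3078 ± 209 to 6135 ± 679 CPM, whereas Gja1 fell by 2.62 ± 0.20. As adjusted p with an estimated correlation, camera gave 0.466 for the TGF-beta and BMP list and 0.560 for the fetal-like list. The TGF-beta list lost its call with the leukocyte and macrophage covariate (0.258), and the fetal-like list without P1 replicate 1 (0.100), 2 (0.0666) or 3 (0.0748) and with the non-epithelial (0.299) and the leukocyte and macrophage covariates (0.312).

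**Figure D3:**
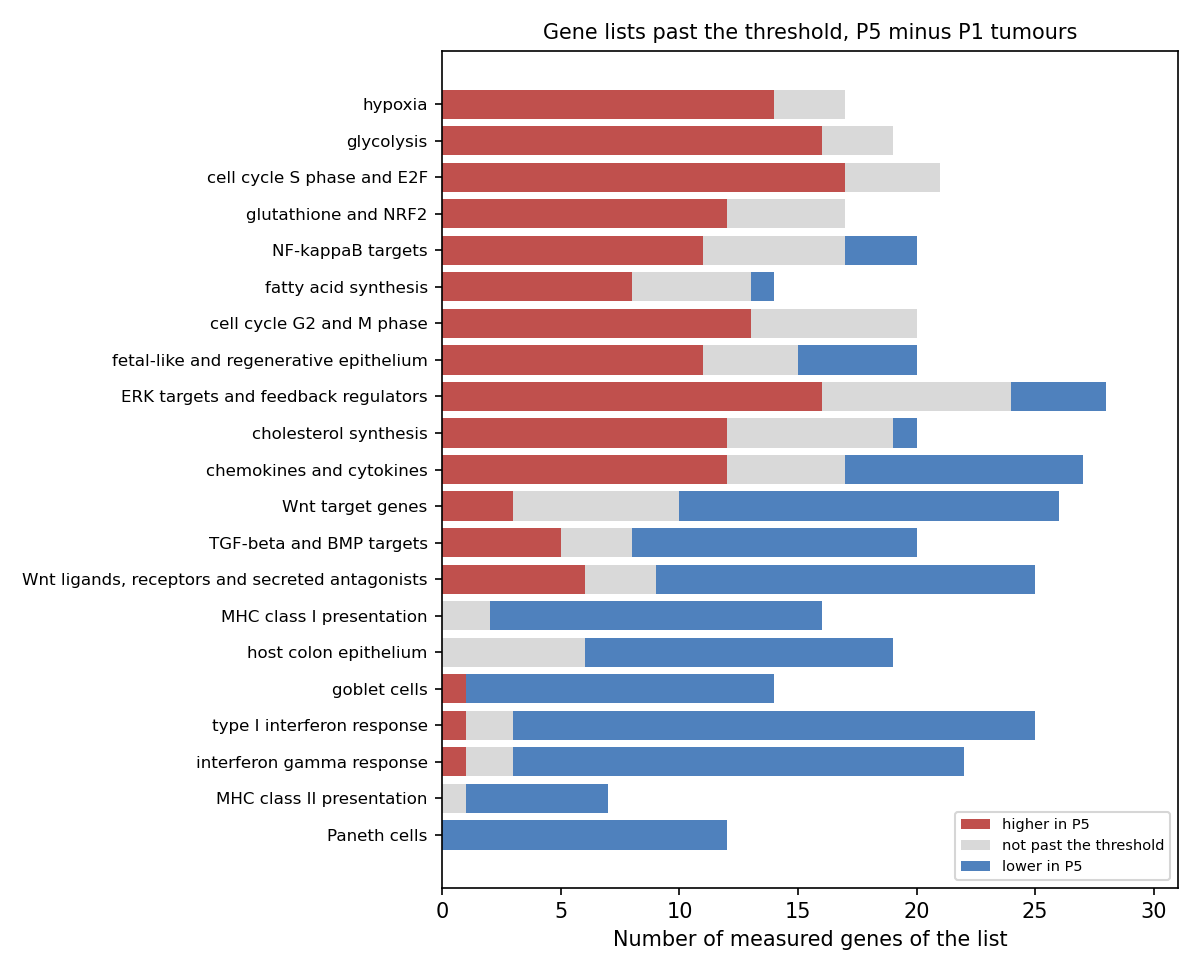
Number of measured genes (x axis) that were higher in P5 (red), lower in P5 (blue) or not past an adjusted p of 0.05 (grey) in each of the 21 lists past the threshold by camera, ordered by median log2 fold change. All 12 Paneth cell genes were lower, and 16 of 19 glycolysis genes were higher.

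Levels of genes with near-identical copies are uncertain, since reads shared between copies may be left out or split by the authors' counting. This covers, among others, the Defa, Reg3, H2-Q, Hbb and Hspa1 families and the glycolysis genes Gapdh, Pgk1 and Pgam1. Ribosomal protein genes may be affected too, as Rpl37 was listed at 1.43 CPM in P1 and 2.75 CPM in P5. Gapdh was listed at 14.2 ± 2.01 CPM in P1 and 35.7 ± 1.58 CPM in P5.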

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

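A value was singled out when 1 of the 4 P1 tumours stood apart from the other 3 by Dixon's test at the 95% level. P5, with 3 tumours, was not tested in this way. Of 285 values tested (named genes, list scores and library totals), 24 stood apart, where chance gives about 1 in 20. The tests of host colon cells on the Paneth list, of leukocytes on the class II list, of random placement and of copy number were chosen after the results were seen, as were the Hox and the leukocyte and macrophage covariates and the list-level values given with the latter.

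P1 replicate 2 was the highest in the macrophage gene Lyz2 (76.77 CPM, others 15.29 to 18.36), the collagen gene Col1a1 (139.4, others 33.82 to 45.95), Gpm6b (4.697, others 1.052 to 1.477) and the mean log2 CPM of the leukocyte list (1.759, others 0.589 to 0.783). P1 replicate 1 was the highest in Irgm2 (69.31 CPM, others 44.2 to 48.46), Psmb9 (27.11, others 15.97 to 17.6) and H2-DMb1 (12.31, others 5.165 to 6.287). It was the lowest in Rbp2 (9.17 CPM, others 12.58 to 12.89), Bnip3 (5.027, others 8.199 to 8.842) and Rpl32 (131.1, others 150.8 to 153.8).

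P1 replicate 3 was the highest in Rgs13 (2.572 CPM, others 1.076 to 1.164), Krt18 (3450, others 2870 to 2879), Bambi (46.01, others 41.62 to 41.98), Myh11 (17.24, others 2.444 to 4.591) and Igf2 (1.069, others 0.3425 to 0.4655), and the lowest in Car4 (11.2, others 17 to 17.98). P1 replicate 4 was the lowest in Dusp6 (286.6 CPM, others 352.2 to 360.3), Wnt6 (97.09, others 136.3 to 137), Grhl2 (63.43, others 82.83 to 86), Nfkbiz (136.4, others 177.4 to 182.1), Jag2 (17.56, others 27.6 to 29.27) and the mean log2 CPM of the Wnt target list (6.595, others 6.911 to 6.972). It was the highest in Cd81 (969.9 CPM, others 770.9 to 794) and the fetal-like list (8.934, others 8.536 to 8.603).

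Of the 35 splits of the 7 tumours into 4 and 3, only the real one (1 split) changed as many as 8399 genes, and the highest of the others changed 0. Each of the other splits puts P1 and P5 tumours in the same arm, which widens the spread within that arm. First of 35 is the strongest result so few splits can give, so chance is not excluded by it. For the Wnt list the real split also came first, with a camera p of 8.73e-10 (1 split as small). The smallest of the others was 7.42e-09, in a split that changed 0 genes. For the MAPK list, 10 of the 35 splits gave a camera p as small as the real 0.00127, and the smallest of the others was 2.48e-05. The other splits keep most P5 tumours in the same arm, so they carry part of the real contrast, and the p ignores direction. This count therefore cannot decide on chance, which is not excluded for that list's rank among genes. The list's mean log2 CPM was 6.215 to 6.495 in the P1 tumours and 6.725 to 6.748 in the P5 tumours.

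Paneth and goblet cell genes were lower in P5 tumours, and so were Hox genes that mark the host colon. Fewer host colon cells in the P5 sorts would lower these genes by no more than the host share fell. With members at 0 set at their bound, the Paneth median lay further down than the Hox median. The difference was -3.818 log2 units (95% bootstrap interval -5.703 to -2.277). This interval resamples genes and does not measure the spread between tumours. None of the 19 host colon genes fell as far as the Paneth median (lowest -3.64). These depths argue against this explanation for the Paneth genes as far as the host colon genes track the share of host cells, which was not measured. For the goblet genes, the median of the 13 that fell was -1.85 before and -1.409 with the Hox score as a covariate (median SE 0.208 and 0.277). With it 8 of 13 stayed past the threshold, which met the condition written against host cells as the cause. The Hox score only stands in for the share of host cells, which was not measured, so host cells are not excluded for the goblet genes. The enteroendocrine (3 of 12 genes lower, median log2 fold change -0.83, adjusted p = 0.183) and tuft cell lists (8 of 12 lower, median -2.62, 0.261) did not pass, whether they differ from the goblet list (median -1.82) was not tested, and a difference between the lines or passages stays open, untested.

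MHC and interferon genes were lower in P5 tumours, and so were 7 of 11 leukocyte and 7 of 12 macrophage markers. A live EpCAM gate should mostly remove the cells that carry these markers. Lyz2 was at 31.5 against 0.672 CPM, with 76.77 CPM in P1 replicate 2 and 15.29 to 18.36 CPM in the other P1 tumours. Neither marker list passed camera (adjusted p = 0.199 and 0.0899), and Cd53 and Mrc1 rose. By fry both lists were lower (adjusted p = 0.0391 for leukocytes and 0.0268 for macrophages). Of 14 alternatives planned beforehand, fry among them, the leukocyte list passed in 1 and the macrophage list in 7. Class II genes fell further than the median leukocyte and macrophage marker (difference of medians -3.134, 95% bootstrap interval over genes -4.961 to -1.875). Yet 2 of 25 leukocyte, macrophage and B cell markers fell as far as the class II median of -5.26. These were Lyz2 (-5.56), whose P1 mean was raised by P1 replicate 2, and Igha, with 1 count in the P5 tumours (ratio of P1 to P5 counts 102, counting interval 18 to 4050). Both are weak grounds, but a lower share of the leukocytes that carry class II is not excluded. With the leukocyte and macrophage score as a covariate, the median of the 14 class I genes that fell went from -1.98 to -1.668 (median SE 0.201 and 0.457), and that of the 40 interferon genes from -2.48 to -2.592 (median SE 0.407 and 0.926). Of the interferon genes 11 of 40 stayed past the threshold, which met the condition written for the leukocyte explanation (under 50%). Of the class I genes 7 of 14 did, which met neither condition. The conditions were written before this test, with a covariate chosen after the data were seen. The standard errors grew with that covariate, which differs between the groups, and why the calls ended was not tested. The lists still passed camera (adjusted p at most 0.00208 and 3.08e-05). For all 3 groups a lower leukocyte share and a lower expression in the tumour cells therefore cannot be told apart.

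Whole chromosomes were shifted between the groups, over 10026 genes with a mean log2 CPM above 3. Median log2 fold changes were 0.48 on chromosome 19, 0.43 on chromosomes 6 and 15, -0.329 on chromosome 14, -0.245 on chromosome 13 and -0.235 on chromosome 10, against 0.0729 over all genes, with the same sign in each of the 3 P5 tumours. Random placement of genes over chromosomes gave no spread as large in 10000 permutations (p = 1e-04, the smallest they can give), and removing trends on GC content, exon length and expression left 94.4% of the spread. On these 6 chromosomes 36 of 36 windows of 20 Mb, or 100% of them, lay on the chromosome's side of the genome median. A difference in chromosome copy number between the lines is a candidate explanation that fits these values, found and tested on the same data, and Kras (chromosome 6) and Myc (chromosome 15) lie on chromosomes with higher medians.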

How the results depend on the processing

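The Hox covariate and the leukocyte and macrophage covariate were chosen after the data were seen. The count of 8399 genes stayed within 1.5 times in all alternatives but 4, which were the 2-fold threshold (3699), the non-epithelial covariate (4202), the Hox covariate (3015) and the leukocyte and macrophage covariate (2474). The added covariates differ between the groups, which widens the errors. Leaving out a library gave 6765 to 8149 genes. The MAPK list lost its call with an estimated correlation (0.5596) and the Hox covariate (0.4652), and its adjusted p was 3.18e-05 to 0.0125 in the others. The Wnt list lost it with an estimated correlation (0.4661). Leaving out a library gave 0.00184 to 0.0103 for MAPK and 8.33e-12 to 1.04e-07 for Wnt. Of the other 50 lists, 19 passed, against 0 with an estimated correlation, 36 with fry, and 17 to 22 without a library. Of the 4 engineered genes 1 passed, against 2 with total counts and 0 with the non-epithelial and the leukocyte covariates. The cause of these differences was not tested.

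Shared replicate numbers did not pair the tumours, as deviations of same-numbered tumours correlated at -0.064, -0.13 and -0.001. With the number as a replicate block, 7556 genes passed, among them 7188 of the 8399 genes called without it. The MAPK list had 0.00565, the Wnt list 6.59e-14, 22 other lists passed and 1 engineered gene did. No list and no engineered gene lost its call, whereas 5 named genes did.

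In the alternatives planned beforehand, results with no call whose direction turned were, with total counts, heat shock (0.9618), T and NK (0.9722) and fibroblast lists (0.8989), Smad4 (0.3409), Dusp6 (0.5602), Ccnd1 (0.2808), Trac (0.9876), Ascl2 (0.8055) and Jak1 (0.7448). With the block they were heat shock (0.6867) and T and NK lists (0.9815), and with fry heat shock (0.9548). With the non-epithelial covariate they were the gastric (0.9313), EMT (0.6906), matrix protease (0.2306), Notch (0.7023), fibroblast (0.02639) and endothelial lists (0.9313), Apc (0.2721), Smad4 (0.8334), Spry2 (0.6396), Trac (0.3753) and Gata6 (0.6211). Leaving out a library turned Apc (0.293 to 0.9555), Smad4 (0.5836 to 0.9001), Ccnd1 (0.4127 to 0.9991), Trac (0.4431 to 0.9777), Col3a1 (0.2562 to 0.9952), Col1a1 (0.03201 to 0.9122) and the matrix protease (0.5229 to 0.8873), heat shock (0.5609 to 0.9484) and fibroblast lists (0.261 to 0.9579), none past the threshold with all libraries. Of named genes with no call, Dusp6, Ccnd1, Lck, Col3a1, Col1a1, Plp1, Ascl2, Slc22a18 and Hnf4a turned with the Hox covariate and Apc, Spry2, Trac and Gata6 with the leukocyte covariate. Among called lists and named genes, direction turned only with the Hox covariate, namely for the host colon list (0.6929), which holds those Hox genes, Hoxb13 (0.5922), Etv4 (0.8696), Ndufa1 (0.9001) and Atp5b (0.7893). Over all 8399 genes the sign turned for 696 with the Hox, 152 with the leukocyte and 54 with the non-epithelial covariate, and for 0 in the other edgeR, DESeq2 and limma settings. Of 212 named genes past the threshold, 49, 65 and 33 lost their call with these 3 covariates (Hox, leukocyte, non-epithelial) and at most 7 in any other setting.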

Other observations

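The other fixed lists held gene changes without passing camera. Of 15 gastric and mucous metaplasia genes, 5 rose and 7 fell (adjusted p = 0.438), with the gastric trefoil gene Tff2 rising from 0.473 ± 0.167 to 16.2 ± 2.66 CPM (SD, n = 4 and 3), Cldn18 from 4.57 ± 1.49 to 55.9 ± 8.69 CPM and Aqp5 by 1.84 ± 0.10 (SE) on the log2 scale, whereas the mucin gene Muc6 fell from 31.2 ± 9.82 to 0.0947 ± 0.0439 CPM. Of 17 squamous and keratin genes, 8 rose and 4 fell (0.135), with Krt4 rising from 202 ± 28.0 to 1022 ± 168 CPM. Of 12 tuft cell genes, 8 fell and 2 rose (0.261), among them Trpm5, which fell by 3.73, whereas Ptgs1 and Avil rose by 1.71 ± 0.13 and 1.65 ± 0.17. Of 11 absorptive enterocyte genes, 7 fell and 1, Rbp2, rose (0.0818), and of 12 enteroendocrine genes 3 fell (0.183). In the EMT and partial EMT list 3 of 17 genes rose and 6 fell (0.320), Vim from 66.9 ± 20.6 to 5.38 ± 2.85 CPM, while Serpine1 rose by 3.81 ± 0.35.

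Further lists moved as follows, with the camera adjusted p in brackets. Of 16 YAP targets 8 rose and 4 fell (0.0980), of 16 epithelial junction genes 5 and 4 (0.320), of 16 Notch pathway genes 6 and 7 (0.723), of 16 matrix protease genes 2 and 6 (0.792), of 15 p53 targets 4 and 3 (0.406) and of 9 cell cycle inhibitors 3 and 2 (0.792). Of 20 unfolded protein response genes 9 rose and 5 fell (0.261), and of 22 heat shock and dissociation genes 5 rose and 9 fell (0.900). Of 25 ribosomal protein genes 9 rose (0.142), of 24 oxidative phosphorylation genes 9 fell (0.205) and of 11 mitochondrial-encoded genes 2 fell (0.320). Among lists of other cells, 2 of 6 neutrophil genes fell (0.320), both of the 2 B and plasma cell genes fell (0.142), 1 of 4 mesothelium and nerve genes fell (0.448), 3 of 7 muscle genes fell and 1 rose (0.261), and none of 3 T and NK cell genes (0.849) or 5 red blood cell genes (0.450) passed in edgeR, with no call over these lists alone. Of the red blood cell genes, 2 had an unadjusted p under 0.05 and 2 passed in DESeq2, and of the T and NK cell genes 0 did in either. The engineered genes gave 0.724 as a list. Counts adjusted over the list alone (higher and lower) were 9 and 5 for squamous genes, 4 and 0 for ribosomal protein genes, 0 and 7 for oxidative phosphorylation, 10 and 6 for the unfolded protein response, 6 and 5 for junctions, 4 and 7 for EMT, 0 and 0 for mitochondrial-encoded genes and 6 and 8 for Notch, and for the other lists in these paragraphs they equalled those given.

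The genes that follow were picked out after their values were seen, and Cdkn1c, Ascl2 and Ltf among them are also members of fixed lists. Of genes in an imprinted cluster on distal chromosome 7, H19 fell from 10.96 ± 3.63 to 0.0540 ± 0.0476 CPM and the cell cycle inhibitor gene Cdkn1c from 199 ± 36.9 to 13.9 ± 4.50 CPM, whereas Phlda2 rose from 21.7 ± 3.37 to 69.2 ± 4.72 CPM and Ascl2 did not pass. Of the interferon receptor genes, Ifngr2 fell by 1.59 ± 0.10, Ifngr1 by 0.90 ± 0.11, Ifnar2 by 0.64 ± 0.12 and Ifnar1 by 0.35 ± 0.08, and Irf9, which acts with Stat1, by 1.83 ± 0.14. Jak2 rose by 1.46 ± 0.11 and the receptor tyrosine kinase gene Met by 1.12 ± 0.10. Gata4, a factor of the proximal intestine, fell by 2.75 ± 0.29, Onecut2 rose by 2.11 ± 0.19, and Cdx2 (88.9 against 70.7 CPM) did not pass. The antimicrobial gene Ltf fell from 314 ± 74.4 to 29.8 ± 34.0 CPM.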
